A study of Mus musculus with 20 samples.

How the data were processed

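Gene expression was measured on 20 cDNA arrays of 2 colours, 5 of normal thymus and 15 of thymic lymphomas from C57BL/6J mice irradiated with gamma rays. Per the labels' protocols, total RNA was extracted, amplified, and labelled with Cy5 for the test sample and Cy3 for the reference, total RNA of several cell lines. The values used were the log ratios of the deposited value table, read as log2 of sample over reference. The labels give neither the base nor the direction. The values were too wide for log10, and a natural log was not excluded. Array medians of -0.07 to 0.04 show ratios centred near 0 on each array, but not on each gene. The scanner, background correction, within-array normalization, spot filter and the merging of spots are not given in the sources used here. Scanner files were not used here, so signal over background per spot is unknown, and only the number of arrays could be set against the precision.

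Samples were grouped by their titles. On lymphoma arrays the source name of the second channel also reads as normal thymus, whereas title and description name a lymphoma, and the title was followed. The irradiation text is the same on all 20 samples. All 20 columns were matched to a sample, and 0 were left over.

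Of 11239 named features in the table, 8401 had 1 current mouse symbol in the gene table of assembly GRCm38.p6: 5562 as written, 17 in other letter case and 2822 through 1 synonym. The other 2838 kept their own names: 61 matched several genes, 2493 were clone names and 284 matched nothing. Features of the same symbol were averaged per array, which concerned 29 genes and left 11210 features, 8372 of them with a symbol. Some symbols are updates of the names deposited, such as Krt8 (Krt2-8), Krt18 (Krt1-18), S1pr1 (Edg1), Irf8 (Icsbp1), Wdr25 (B930090D16Rik), Prmt7 (BC006705), Ube2z (D11Moh35), Agfg1 (Hrb), Slc45a3 (Pcanap6), Rmnd5a (1110007A06Rik) and Trbv13-2 (Tcrb-V8.2). In 214 pairs of features the values were identical under 2 names, and in 4 of these pairs the names led to different symbols. No coordinates were used beyond the order and chromosome of genes in that assembly.

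Features needed a value on at least 3 normal and 8 lymphoma arrays. Lymphoma and normal thymus were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, and calls use limma with Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 5 measured members were tested with cameraPR at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists. There were 25 lists: thymocyte identity, immature and mature thymocytes, Notch pathway, cell cycle, p53 targets, DNA break repair, apoptosis, Eph receptors, Myc targets, glycolysis, oxidative phosphorylation, ribosomal proteins, interferon response, cancer genes of radiation lymphoma, and markers of 10 other cell types. The direction of the ratios was tested with one-sided exact sign flips over the 5 normal arrays. The RB lymphomas were set against the other lymphomas with the same limma fit. The spread between samples was compared through the median log2 ratio of SDs over the 11197 features with all values, with 100 permutations of the group labels over group-centred arrays.

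The design, the lists, the genes of interest and the alternatives were fixed before the data were examined, apart from 4 alternatives named in the closing part on processing. Named genes are the 15 with the largest rise and the 15 with the largest fall among genes with a symbol, past the threshold and with at least 12 of 15 lymphomas on that side of the normal mean. They also include up to 4 members of each list with the smallest adjusted p, 23 genes of interest whatever their result, and the 10 genes of largest SD among lymphomas. A part of the rule for the RB comparison named no gene. Some genes that these rules name are not reported. Any other gene is said to have been chosen or named after its value was seen, and its call was not rerun under the alternatives.

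Alternatives covered array scaling, the filter on missing values, averaging of features, the variance model, array weights, leaving out each array, each set of lymphomas alone, and a stricter threshold of 0.01. The fit was tested on simulated data for this comparison with 11210 features. It recovered 41 of 67 features changed by 0.5 on the log2 scale (61.2%), 62 of 67 changed by 1 (92.5%) and 66 of 66 changed by 2, and called 14 of 10990 unchanged ones. A simulated list had adjusted p = 1.22e-08, and 0 other lists passed. Simulated features varied independently of one another and with the same spread on all arrays. These rates therefore do not carry over to lists whose members vary together, or to arrays of unlike ratio range. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.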

Results

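The series measured gene expression in the thymus of C57BL/6J mice, an inbred laboratory strain, with 2-colour cDNA arrays. Each of the 20 arrays compared 1 test RNA, labelled with Cy5, with a common reference RNA from a pool of cell lines, labelled with Cy3. There were 5 arrays of normal thymus and 15 arrays of thymic lymphomas. The lymphomas arose in mice given 4 weekly doses of 1.75 Gy of gamma radiation from 4 weeks of age. Whether the normal thymuses came from unirradiated mice is not stated in the labels, nor that each array is a separate animal, so p-values measure the spread between these samples. The deposited values were log ratios for 11239 rows, of which 24 single values were missing. Array medians lay between -0.07 and 0.04. The SD over the rows of an array ran from 0.47 on the array of lymphoma 8 to 0.97 on that of lymphoma 10, so arrays differed in how far their ratios spread, and the number of arrays limits the precision. Among normal thymuses the correlation across features between 2 arrays was 0.853 at the median, among lymphomas 0.796, and between the groups 0.71. These are correlations across genes, which are not independent replicates.

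The values were read as log2 of sample over reference, since the labels give neither the base of the log nor the direction of the ratio. On all 5 normal thymus arrays, genes of thymocyte identity, such as those of the T-cell receptor complex, stood above connective tissue genes. The median difference was 3.50 on the log2 scale. Thymocyte genes also stood above thymic epithelial genes by 2.06 at the median on 5 of 5 arrays. Each one-sided exact permutation test by sign flips gave p = 0.0312, the smallest that 5 arrays allow. The base remains an assumption: a natural log would make every log2 difference below larger by 1 constant factor, with the same signs and p-values, and would change the folds and the counts past a given size.

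The first comparison asked which genes differ between radiation-induced lymphomas and normal thymus. Lymphomas had lower levels of antigen presentation and epithelial genes, and higher levels of Myc and of genes for growth and DNA replication. The largest falls were those of Ube2z, a ubiquitin-conjugating enzyme, and H2-Aa, an MHC class II chain that presents peptides to CD4 T cells. Ube2z and H2-Aa each fell by 3.66. H2-Aa averaged 6.27 ± 0.69 (SD, n = 5) in normal thymus and 2.61 ± 1.39 (SD, n = 15) in lymphoma, 12.6-fold lower, with limma adjusted p = 0.000246. After quantile normalization H2-Aa fell by 1.95 (adjusted p = 0.0171) and Ube2z by 2.95. Keratin 8 (Krt8), a filament protein of epithelial cells, fell by 2.48 and keratin 18 (Krt18), its partner, by 2.33. Myc, a transcription factor that drives cell growth, rose from -0.36 ± 0.21 (SD, n = 5) to 0.81 ± 0.46 (SD, n = 15), a 2.25-fold increase, with all 15 lymphomas above the highest normal thymus.

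In all, 1035 features were higher and 1227 lower in lymphoma at an adjusted p under 0.05 among 11210 tested, which is 20.2% of them. A change of at least 1 on the log2 scale was met by 35 of the higher and 184 of the lower features, and after quantile normalization by 56 and 111. The median change over all features was -0.03. At an unadjusted p under 0.05, 3636 features differed. For 233 features every lymphoma lay above every normal thymus, and for 266 every lymphoma lay below; chance gives each of these to 1 feature in 15504. Without normal thymus 5, whose array had the largest SD over features among the normal ones, the lower features numbered 802.

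Among genes with a current symbol, the largest rises were in Wdr25, a WD-repeat protein, Gfra1, a co-receptor for the growth factor GDNF, and Ccrl2, a receptor that binds chemerin. Wdr25 rose by 2.16 ± 0.51 (SE), Gfra1 by 2.13 ± 0.43 (SE) and Ccrl2 by 2.12 ± 0.28 (SE). Wdr25 and Ccrl2 were higher in 15 of 15 lymphomas than in any normal thymus, and Gfra1 in 14. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 1.67, and the arginine methyltransferase Prmt7 by 1.57. Dut, which removes dUTP and keeps uracil out of DNA, rose by 1.31, and Mif, a cytokine, by 1.22. Cct8, a subunit of the chaperonin that folds actin and tubulin, rose by 1.17. The rises of Agfg1 (1.38), Chdh (1.29), Pdgfrb (1.28) and Slc45a3 (1.26) completed the group with that of Fbln1, an extracellular matrix protein. Fbln1 rose by 1.29 at adjusted p = 0.0309, a call lost without any 1 of normal thymuses 1, 2, 3 or 5 (adjusted p from 0.0571 to 0.0773), with only the 8 lymphomas whose names start with RB (0.147) and without the 6 arrays of widest ratios (0.0905). The call of Agfg1 was lost without normal thymus 3 (adjusted p = 0.053) and with the RB lymphomas alone (0.79, adjusted p = 0.108), and its rise ran up to 2.05 in another alternative. That of Chdh was lost without the 6 arrays of widest ratios (adjusted p = 0.076). Those 6 arrays, with an SD over features above 0.8, were normal thymuses 3 and 5 and lymphomas 9, 10, 12 and 13, all of them RB. Leaving them out therefore also leaves fewer normal arrays and fewer RB lymphomas.

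Other large falls included Scd1, the desaturase that makes monounsaturated fatty acids, which fell by 3.41 ± 0.33 (SE). Crip3, a thymus LIM protein, fell by 3.01. Ctsl, the cathepsin that cortical epithelium uses to process antigens for CD4 T-cell selection, fell by 2.94. Cxcl12, a chemokine of the thymic stroma, fell by 2.74. Cbr2, a carbonyl reductase, fell by 2.62 and Cstb, a cathepsin inhibitor, by 2.26. Each of these genes, and Ube2z, was lower in 15 of 15 lymphomas than in any normal thymus. Znrf1, Epsti1, Rab6b and Rmnd5a fell by 2.08 to 2.23.

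**Figure D1:**
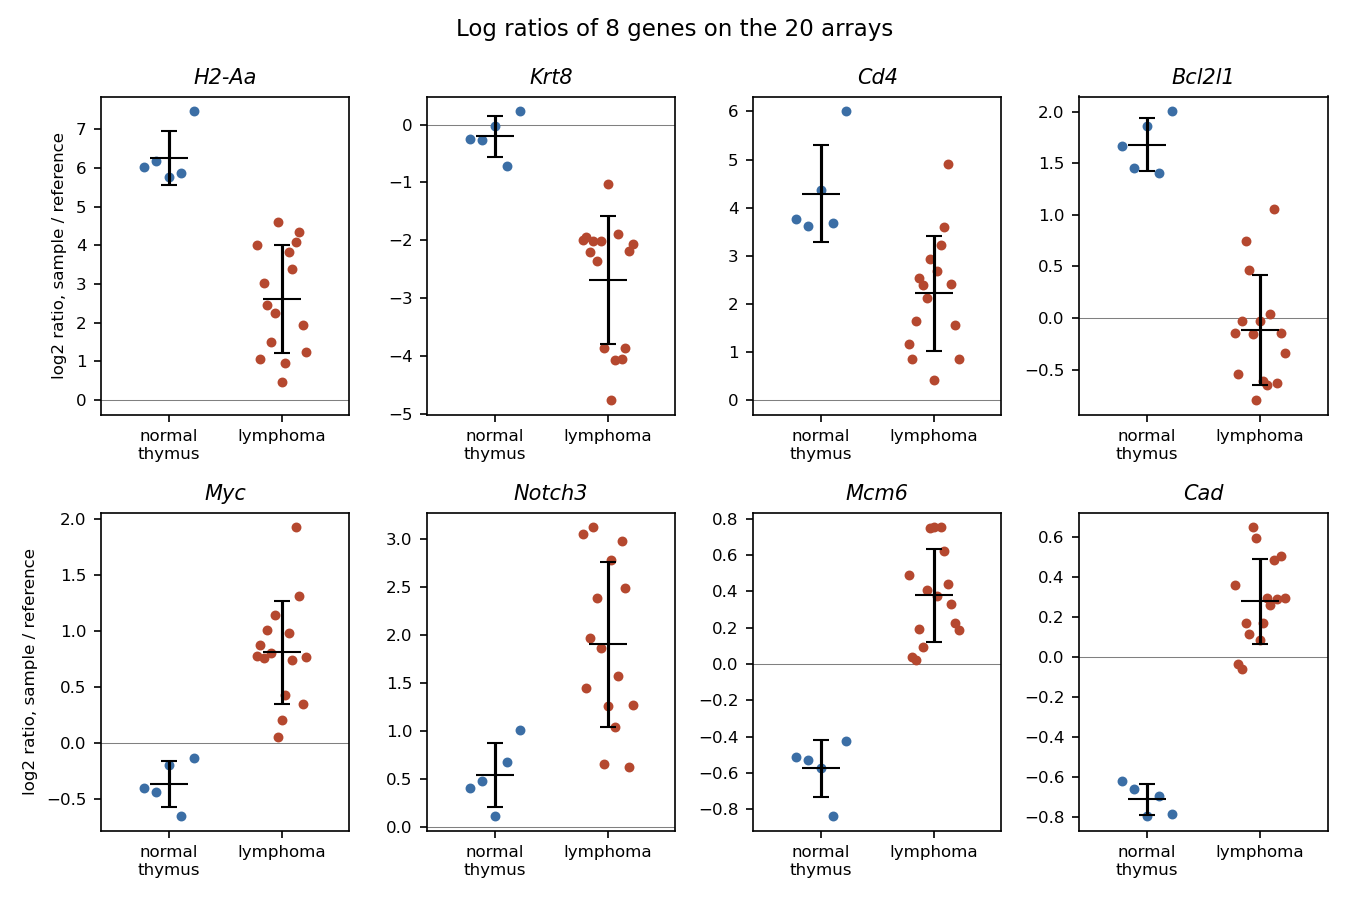
Log2 ratio of sample over reference (y axis) of 8 genes on each array, for 5 normal thymuses (blue points) and 15 lymphomas (red points). The bars are the group mean ± SD; H2-Aa, Krt8 and Bcl2l1 lie lower in 15 of 15 lymphomas than in any normal thymus, Myc, Mcm6 and Cad higher, and Cd4 and Notch3 overlap.

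Gene lists fixed beforehand were tested as groups with limma's camera at a preset correlation, and 5 of 23 tested lists were higher and 6 lower in lymphoma. With an estimated correlation 2 were higher and 4 lower. With fry, which tests a list against no change, all of the 5 and 6 but thymocyte identity also passed (adjusted p up to 0.00189). The list of Myc targets and ribosome biogenesis was the furthest up. Of its 40 measured members 31 rose and none fell, 34 rising when adjusted over the list alone. Its median change was 0.61, with adjusted p = 4.81e-24 and adjusted p = 0.0143 with an estimated correlation. Cad, which starts pyrimidine synthesis, rose by 0.99 and the nucleolar protein Npm1 by 0.93. Shmt2, the mitochondrial enzyme that feeds serine carbon into folate metabolism, rose by 0.90.

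Cell cycle and DNA replication genes rose in part. Of 62 measured members 24 rose and 2 fell, or 31 and 2 adjusted over the list alone, with a median change of 0.31. The list had adjusted p = 6.06e-12, and adjusted p = 0.0439 with an estimated correlation. The risers included Mcm6, part of the helicase that opens replication origins (0.95), Cdk4, a kinase of the G1 phase (0.79), and Cks1b (0.79). Mki67, a proliferation marker, averaged 0.45 higher without passing the test (adjusted p = 0.238), as did Top2a at 0.12; both were chosen after their values were seen. The 2 members that fell were D-type cyclins, partners of Cdk4: Ccnd2 fell by 1.45 ± 0.25 (SE) in 15 of 15 lymphomas, and Ccnd3 by 0.78. The Ccnd3 call was lost without normal thymus 2, 3 or 5 (adjusted p from 0.0613 to 0.0872) and under quantile normalization (-0.42), with scaled arrays (0.128), with the lymphomas other than RB (0.0682) and without the 6 arrays of widest ratios (0.111), whereas that of Ccnd2 held at an adjusted p under 0.05 in every alternative run.

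DNA break repair, glycolysis and cytosolic ribosomal proteins passed upward at the preset correlation, but none of these lists passed at the estimated one. In the repair list 12 of 31 measured members rose and 1 fell, or 13 and 1 adjusted over the list alone, with the checkpoint kinase Chek1 up by 0.72. The single fall was that of Xrcc4, a factor of end joining (-0.33), named after its value was seen. The list had adjusted p = 9.68e-05, and adjusted p = 0.0912 with an estimated correlation. In glycolysis 9 of 20 rose and none fell, 11 rising when adjusted over the list alone. They included Ldha, which makes lactate (0.92), Pgk1 (0.95) and Eno1 (0.74). With arrays scaled to the same range the Eno1 call was lost (0.50, adjusted p = 0.0651) and the rise of Pgk1 was 0.53 (adjusted p = 0.0482). This list had adjusted p = 2.38e-05, and adjusted p = 0.14 with an estimated correlation. Of 65 ribosomal proteins 31 rose and none fell, 42 rising when adjusted over the list alone, with Rpl3 up by 0.67 and Rpl32 by 0.60. The list median was -0.47 in normal thymus 3, -0.26 in 5 and -0.11 in 1, but -0.01 in 4 and 0.03 in 2, inside the lymphoma range of -0.01 to 0.29. Their adjusted p was 7.52e-14, and adjusted p = 0.107 with an estimated correlation.

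Antigen presentation on MHC class II fell as a list, with the smallest p among falling lists at the preset correlation but not at the estimated one. Of 10 measured members of that list, which also holds dendritic cell genes, 7 fell, or 8 adjusted over the list alone. Besides H2-Aa they included H2-Eb1 (-2.99) and H2-DMa, which loads peptides onto class II molecules (-1.47). The costimulatory ligand Cd86 (-0.89) and Irf8, a transcription factor of dendritic cells (-1.15), were others. After quantile normalization H2-Eb1 changed by -1.93 (adjusted p = 0.00325). The list had adjusted p = 1.02e-09, and adjusted p = 0.0182 with an estimated correlation. Itgax (-0.08) and Zbtb46 (-0.10), markers of dendritic cells, did not pass the test and were chosen after their values were seen.

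Thymic epithelial genes fell as a group. Of 9 measured markers 5 fell, or 7 adjusted over the list alone, with adjusted p = 7.26e-05 and adjusted p = 0.0182 with an estimated correlation. Keratin 5 (Krt5), of medullary epithelium, fell by 1.54 and Ly75, an endocytic receptor of cortical epithelium and dendritic cells, by 0.63. Without the 6 arrays of widest ratios Ly75 changed by -0.37 (adjusted p = 0.0197). Epcam, named after its value was seen, fell by 0.92 (adjusted p = 0.0424). The medians of the 9 genes ran from -0.29 to 0.42 on the normal arrays and from -1.95 to -0.37 on the lymphoma arrays. Of 5 measured adipocyte genes Scd1 and Cd36, a fatty acid transporter (-1.84), fell, or 3 adjusted over the list alone. Cd36 in normal thymus 3 (0.044) lay inside the lymphoma range of -1.148 to 0.905. The list median ran from 0.04 in normal thymus 3, inside the lymphoma range of -0.89 to 0.12, to 2.77 in normal thymus 4. That list had adjusted p = 0.00101, and adjusted p = 0.177 with an estimated correlation.

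Genes of the interferon response and of mature thymocytes fell too. In the interferon list 10 of 23 members fell and 1 rose, or 11 and 1 adjusted over the list alone. The interferon-induced genes Ifit1, Ifi35 and Ifit3 fell by 1.30, 1.01 and 0.74, whereas Irf7, named after its value was seen, rose by 0.51. The list had adjusted p = 5.79e-07, and adjusted p = 0.0182 with an estimated correlation. Of 16 genes of mature thymocytes and emigration 9 fell and none rose, also 9 adjusted over the list alone. S1pr1, the receptor that lets thymocytes leave the thymus, fell by 1.08, Slfn1, a gene of the Schlafen family, by 1.17, and the MHC class I genes H2-K1 and H2-D1 by 1.04 and 1.45. That list had adjusted p = 3.47e-07, and adjusted p = 0.0439 with an estimated correlation. Il7r (-0.10), chosen after its value was seen, did not pass the test.

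Thymocyte identity genes were lower as a list, but this depended on the scaling of the arrays. The list stayed called lower without the 6 arrays of widest ratios. Of 26 measured members 7 fell and 1 rose, or 11 and 1 adjusted over the list alone, with a median change of -0.63. The coreceptors Cd4 and Cd8a fell by 2.07 ± 0.55 (SE) and 1.98 ± 0.59 (SE), and Satb1, a chromatin organiser of thymocytes, by 1.77. Cd3e, a chain of the receptor complex, averaged 0.51 lower (adjusted p = 0.515), and Cd2 0.47 higher, neither passing the test, although Cd3e passed without the 6 arrays of widest ratios (-0.81, 0.0216). The list had adjusted p = 0.019, but adjusted p = 0.681 with an estimated correlation, 0.773 after quantile normalization, 0.344 with arrays scaled to the same range, 0.185 with the RB lymphomas alone, 0.0547 without normal thymus 5 and 0.119 with fry. The calls of Cd4 (adjusted p = 0.0772) and Cd8a (adjusted p = 0.669) were lost after quantile normalization and without normal thymus 5 (0.0555 and 0.096) and with the RB lymphomas alone (0.084 and 0.134), that of Cd8a also with scaled arrays (0.0613) and with a trended, robust variance (0.0557), and that of Satb1 after quantile normalization (0.095).

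**Figure D2:**
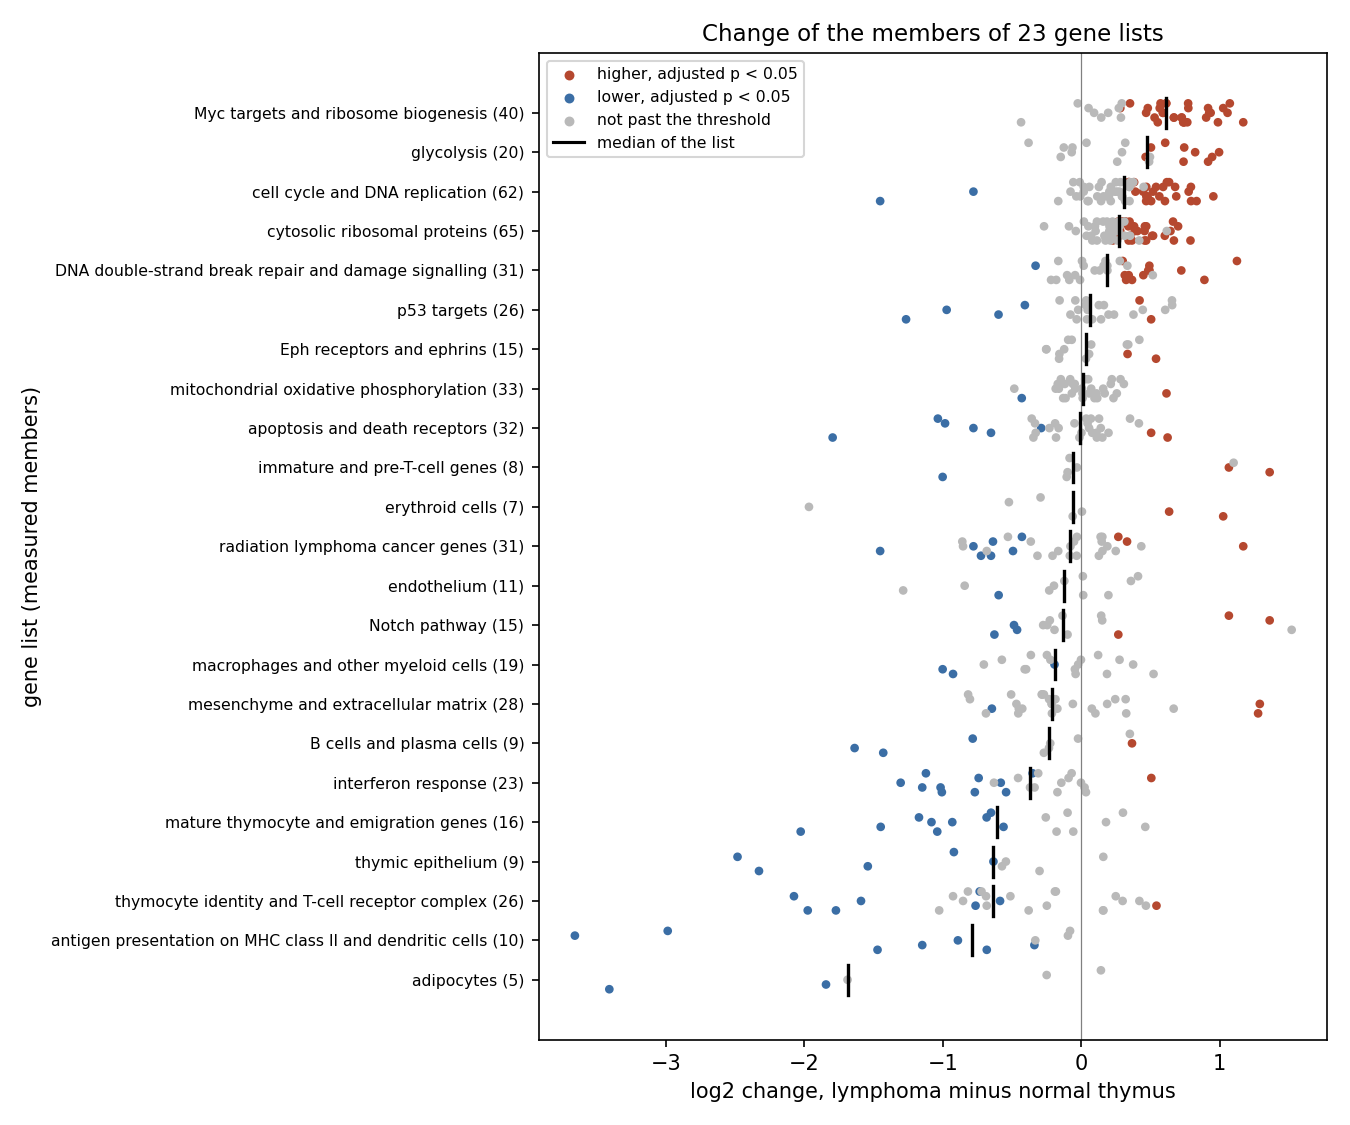
Log2 change of each measured member of the 23 tested lists (x axis, lymphoma minus normal thymus) with the number of measured members in brackets. Points are genes, red or blue where they passed the test upward or downward, and black bars are list medians, which run from -1.69 for 5 adipocyte genes to 0.61 for Myc targets.

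Other lists fixed beforehand did not pass as groups with camera. With fry, apoptosis genes passed downward (adjusted p = 0.0219). In the Notch pathway, which controls T-cell commitment, 3 of 15 members rose and 3 fell, or 4 and 3 adjusted over the list alone, with adjusted p = 0.63, a median of -0.14 and a mean of 0.12. The receptor Notch3 rose by 1.36 ± 0.37 (SE), Nrarp, a feedback target of Notch, by 1.07, and Fbxw7, which tags Notch for degradation and was named after its value was seen, by 0.27 (adjusted p = 0.0495). Ncstn (-0.49), part of the gamma-secretase that cleaves Notch, fell, as did Rfng (-0.63). The Nrarp call was lost without any 1 of normal thymuses 1 to 4 (adjusted p from 0.0546 to 0.0609) and that of Ncstn without normal thymus 5 (0.0502). Without the 6 arrays of widest ratios, Notch3 (0.0646), Nrarp (0.0801) and Ncstn (0.211) did not pass, nor did Ncstn with the lymphomas other than RB (0.0804). Of 8 immature and pre-T-cell genes, 2 rose, Notch3 and Nrarp, and 1 fell, also 2 and 1 adjusted over the list alone. The fall was that of Spi1, a factor of early progenitors and myeloid cells, from 0.98 to -0.02 on average, with adjusted p = 0.628 for the list, a median of -0.06 and a mean of 0.28. Spi1 in normal thymuses 3 (-0.243) and 5 (0.099) lay inside the lymphoma range of -0.465 to 0.308, so its fall rests on normal thymuses 1, 2 and 4. The Spi1 call was lost with the lymphomas other than RB (adjusted p = 0.0681). Without the 6 arrays of widest ratios, which include normal thymuses 3 and 5, Spi1 changed by -1.73. Il2ra, the interleukin 2 receptor chain of early thymocytes, averaged 1.10 higher without passing (adjusted p = 0.255).

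Apoptosis genes split. Of 32 measured members 6 fell and 2 rose, with adjusted p = 0.259 for the list. Bcl2l1, which protects double-positive thymocytes from death, fell by 1.80 ± 0.23 (SE) and Bcl2, another survival protein, by 0.65, both in 15 of 15 lymphomas below every normal thymus. Birc3 fell by 0.78 and Traf1 by 0.98. Without the 6 arrays of widest ratios Birc3 changed by -0.46 (adjusted p = 0.00546). The death-promoting Bid and Bax, named after their values were seen, rose by 0.62 and 0.50. Among 26 p53 targets 4 fell and 2 rose (list adjusted p = 0.833): Perp fell by 1.27, Btg2 by 0.97, Ddb2 by 0.60 and Mdm2 by 0.41, while Bax and Aen (0.42, also named after its value was seen) rose. Of 15 Eph receptors and ephrins 2 rose, Ephb2 (0.54) and Epha3 (0.33), with adjusted p = 0.626. Of 33 genes of oxidative phosphorylation Atp5g1 rose by 0.62 and Ndufs4 fell by 0.43, also with list adjusted p = 0.626, a call the list gained without normal thymus 4 (adjusted p = 0.0341). The Ephb2 call was lost without normal thymus 2 or 5 (adjusted p = 0.0525 and 0.0615), and that of Epha3 without 2, 3 or 5 (0.0508 to 0.14) and in other alternatives, such as without the 6 arrays of widest ratios (0.12, 0.552). Those of Atp5g1 (0.176) and Mdm2 (0.088) were lost without the 6 arrays of widest ratios. Adjusted over the list alone, these 4 lists gave the same counts per direction.

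The list of cancer genes of radiation lymphoma was tested, and the genes of interest, not all of them in that list, were looked up whatever their result. Of 31 measured members of that list 3 rose and 7 fell, also 3 and 7 adjusted over the list alone, with adjusted p = 0.243. Ikzf1, a zinc finger factor of lymphocyte development, averaged 0.68 lower (adjusted p = 0.0809) with 9 of 15 lymphomas below every normal thymus, and Bcl11b 0.85 lower (adjusted p = 0.11) with 11 of 15 below. Ikzf1 passed without lymphoma 9 or 13 (adjusted p = 0.0446 and 0.0439), and Bcl11b without lymphoma 10 or 13 (0.0433 and 0.0401). Both passed with array weights (Ikzf1 -0.82, 0.00728, Bcl11b -1.39, 9.92e-05) and with the lymphomas other than RB (Ikzf1 -0.78, 0.0332, Bcl11b -1.19, 0.00228), and Bcl11b also without the 6 arrays of widest ratios (-1.52, 0.000295). Trp53 (0.13), Cdkn2a (-0.03), Cdkn2b (0.43), Cdkn1a (-0.08), Fasl (0.15), Lef1 (0.25) and Dntt (-0.18) did not pass the test, but Dntt passed with array weights (-0.97, 0.0172) and without the 6 arrays of widest ratios (-1.10, 0.0192). Of 23 genes of interest 16 were measured, and Notch1, Fas, Epha7, Ephb6, Rag1, Rag2 and Ptcra were not analysed here.

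Markers of other cell types that a thymus can hold did not pass as groups with camera. With fry, B-cell and plasma cell genes (adjusted p = 0.00656) and endothelial genes (0.034) passed downward. Of 28 connective tissue genes 2 rose, Pdgfrb and Fbln1, and 1 fell, S100a6 (-0.65), with adjusted p = 0.757. Of 11 endothelial genes Flt1 alone passed the test (-0.60, list adjusted p = 0.626). Among 9 B-cell and plasma cell genes Blk (-1.64), Xbp1 (-1.43) and Ms4a1 (-0.78) fell and Sdc1 (0.37) rose (list adjusted p = 0.137), or 3 and 2 adjusted over the list alone. Blk in normal thymus 3 (-0.628) lay inside the lymphoma range of -1.621 to -0.159. Of 19 myeloid genes S100a8 (-0.93), Spi1 and Mpo (-0.19) fell (list adjusted p = 0.213). S100a8 in normal thymus 3 (-0.06) lay inside the lymphoma range of -0.549 to 0.102. Of 7 erythroid genes 2 rose, Tfrc by 1.03 among them (list adjusted p = 0.757), with a list median of -0.06 although its test pointed up. Tfrc, the transferrin receptor, is also in the Myc target list. Adjusted over the list alone the connective tissue, endothelial and myeloid counts were the same, and 1 erythroid gene also fell. The B-cell list passed without normal thymus 5 (adjusted p = 0.0481), after quantile normalization (0.0141), with arrays scaled to the same range (0.01) and without the 6 arrays of widest ratios (0.0287), the connective tissue list with scaled arrays (0.0398), and the myeloid list without the 6 arrays of widest ratios (0.000808). The calls of S100a6, Ms4a1, Sdc1 and Mpo were each lost without single normal thymuses: 1, 2 or 4 for S100a6 (adjusted p up to 0.107), any of the 5 or lymphoma 7 for Ms4a1 (up to 0.0903), 3 or 5 for Sdc1 (up to 0.0871) and 1 or 5 for Mpo (up to 0.0642). Natural killer genes, with 3 measured, and skeletal muscle genes, with 4, were too few to test as groups. None of the 3 passed alone, and of the 4 Eno3 (0.65) rose and Acta1 (-0.62) fell. The Eno3 call was lost without normal thymus 2, 4 or 5 (up to 0.107), and that of Acta1 without normal thymus 1, 2, 3 or 5 or lymphoma 1, 3, 5, 10, 13, 14 or 15 (0.0503 to 0.19). Other alternatives ended these calls with larger adjusted p: quantile normalization for S100a6 (-0.19, 0.691), leaving out the 6 arrays of widest ratios for Ms4a1 (-0.58, 0.133), Sdc1 (0.13, 0.313) and Acta1 (-0.18, 0.612), scaled arrays for Eno3 (0.31, 0.476) and the RB lymphomas alone for Mpo (-0.17, 0.162).

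Within the lymphomas, the 8 tumours whose names start with RB were compared with the 7 others, since the labels do not say what the name prefixes mean. With limma, 0 of 11210 features differed at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 776, and the lowest adjusted p was 0.667. Each set against the normal thymuses, the RB lymphomas gave 701 higher and 820 lower features and the others 826 and 998. The prefixes RB, 16CG, 19CG and NRH were borne by no normal thymus, and the prefix M by normal thymuses alone. The prefix H was borne by 3 normal thymuses and 2 lymphomas, and these 5 arrays alone gave 36 higher and 100 lower features, with 1835 at an unadjusted p under 0.05. These 5 arrays are also part of the full comparison. Outside prefix H, differences between lymphoma and normal thymus cannot be told apart from differences between prefixes.

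The last comparison asked whether lymphomas differed more from one another than normal thymuses did. The median SD of a feature was 0.24 among lymphomas and 0.23 among normal thymuses, and 56.2% of 11197 features with complete values had the larger SD among lymphomas. The median ratio of the SDs was 1.10, no larger than label permutations gave (two-sided permutation p = 0.921, 100 permutations). Without normal thymus 3 the median log2 ratio of the SDs was 0.43 in place of 0.14, inside the permuted range of -0.36 to 0.67. The genes of largest SD among lymphomas included Aldh1b1, a mitochondrial aldehyde dehydrogenase, at 1.43 ± 1.81 (SD, n = 15) against -0.42 ± 0.20 (SD, n = 5) in normal thymus (adjusted p = 0.0919), passing with array weights (0.0432) and with the lymphomas other than RB (0.0132). The others were Hbb-bh1, Spryd7, Mycl, Cd2, Il2ra, Kbtbd12, Gzma, Hba-a1 and Trbv13-2, a variable segment of the T-cell receptor beta chain. Trbv13-2 alone among the 10 passed the test between the groups (-2.01, adjusted p = 0.0234), a call lost without normal thymus 1, 2 or 5 (0.0501 to 0.0585), after quantile normalization (-0.84), with scaled arrays (0.173) and without the 6 arrays of widest ratios (0.0514). Their SDs among lymphomas ran from 1.44 to 1.87. Hba-a1, a haemoglobin chain, averaged 1.97 lower in lymphoma (adjusted p = 0.0529) and passed without normal thymus 3 (0.0221) or lymphoma 5, 9 or 10 (0.00762 to 0.0436), with each array's median subtracted (0.0484), with array weights (0.000688), with the lymphomas other than RB (0.0461) and without the 6 arrays of widest ratios (0.00167).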

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

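The test of keratin levels and the scaling of arrays to the same range were chosen after the result was seen; the other tests of this part were planned. Among the 5 normal thymuses, 161 results were searched for a sample far from the other 4, and 11 had one. Chance gives about 1 such sample in 20 results, and genes on an array are not independent. Normal thymus 5 stood above the others in 9 of them. H2-Aa was 7.478 there against 5.77 to 6.17 in the others, H2-Eb1 6.456 against 4.53 to 5.03, and Ube2z 4.648 against 3.72 to 3.98. Znrf1 was 4.102 against 3.40 to 3.55, Epsti1 3.31 against 2.31 to 2.58, and H2-K1 1.191 against 0.51 to 0.62. Bcl2 was 0.93 against 0.34 to 0.45, Aif1, a macrophage gene, 2.301 against 0.86 to 0.98, and Ckm, a muscle creatine kinase, 0.659 against 0.18 to 0.32. Normal thymus 3 stood below the others in Ddb2, at 0.27 against 0.80 to 0.86, and in Aldh1b1, at -0.754 against -0.41 to -0.28. Normal thymus 5 also had the largest SD over features of the 5, 0.87.

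More features differed between lymphoma and normal thymus than in any other split drawn, though 100 splits cannot show a share below 1 in 100. Of 100 splits of the 20 arrays into 5 and 15, 1 gave as many called features, the real one with 2262, and the highest other gave 1653. That other split set 5 lymphomas apart from all other arrays, which points to structure among the arrays, whose kind was not tested; splits with 1, 2 or 3 normal thymuses on the small side gave at most 338, 451 and 0. For RB against other lymphomas, where limma called 0 features, 100 of 100 splits necessarily gave as many, so the count of splits decides nothing; the highest other gave 386, and whether tumours, the wider ratios of some arrays or chance lie behind it was not tested.

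Thymocyte identity genes were lower in lymphoma, and the arrays of lymphomas had a somewhat narrower range of ratios, with a median absolute deviation of 0.449 against 0.483 at the median. In the 5 lymphoma arrays whose range was at least the normal median, the list changed by -0.164 at the median (-0.1644, bootstrap interval -0.35 to 0.47). The bootstrap resampled the genes of the list, which vary together, and not the arrays, so its interval gives no spread between tumours. With all arrays scaled to the same range, the list changed by -0.26 (adjusted p = 0.344). Of the 5 arrays of wider range, lymphomas 9, 10, 12 and 13 are RB, so range and prefix cannot be told apart there. Without the 6 arrays of widest ratios, however, the list stayed called lower. With the arrays of prefix H alone it changed by -0.68 at the median (camera adjusted p = 3.31e-05). The fall may come in part from a narrower ratio range, which would draw high ratios such as those of Cd8a towards 0. These results do not put the whole fall down to that range. A change in the tumour cells themselves stays open and was not tested apart from the range.

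Epithelial and MHC class II genes were lower in lymphoma, and 2 technical readings were weighed. A narrower ratio range draws ratios towards 0, but Krt8 and Krt18 were near 0 in normal thymus and lay at -2.49 (-2.4885, the higher of the 2 means) in lymphoma, which argues against this reading for the keratins. A smaller share of all cells other than thymocytes could lower these genes too: the epithelial and MHC class II members above the reference lay at percentiles 0.22 and 0.7 of matched random lists. The endothelial, B-cell and myeloid members lay at 16.3, 34.6 and 39.54, neither in the lowest 5 percent nor above the middle, as did the erythroid members at 28.4, whereas the adipocyte members lay at 1.12. Of these other types only the adipocyte members thus lay near the first lists, and the rest were in between, on 3 to 14 members each. This reading and a loss of epithelium and antigen-presenting cells in particular therefore cannot be told apart. No count of cells was analysed here.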

How the results depend on the processing

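The scaling of arrays to the same range, keeping identical features once, leaving out the 6 arrays of widest ratios and using the arrays of prefix H alone were chosen after seeing the data; all other alternatives were planned. No called result reversed. Of the counts of features, array weights gave 1617 higher and 2040 lower, and the cause was not tested; an adjusted p under 0.01 gave 529 and 597, as a stricter threshold must. Quantile normalization gave 56 higher and 111 lower by at least 1 on the log2 scale, and the cause was not tested. Camera with an estimated correlation called 2 lists higher in place of 5 and 4 lower in place of 6, since it allows for members that vary together. Without 1 array, the higher features ranged from 794 to 1051 and the lower from 802 to 1256, those higher by at least 1 from 32 to 38, and those lower by at least 1 reached at most 197. Lists and the SD ratio were rerun without each normal array only: lists higher ranged from 5 to 6, lists lower from 6 to 6 and the log2 SD ratio from 0.04 to 0.43. The lowest counts of called features came without normal thymus 5, which kept 67.4% of the calls; 5 normal arrays become 4, and the cause was not tested further. Scaled arrays gave 931 and 1121, median-subtracted arrays 981 and 1317, and arrays without the 6 widest 913 and 1259, with 77.2%, 97.3% and 64.1% of the calls kept. Over 136 named genes and 34 alternatives, 137 results lost the threshold, 59 gained it and 0 reversed; for lists 9 lost and 7 gained it. Of 101 named genes that were called, 27 changed by over 1.5 times more or less in some alternative, 11 of them under quantile normalization and 0 without 1 array. The 5 arrays of prefix H alone, 3 normal and 2 lymphoma, gave 36 higher and 100 lower features and 82 lower by at least 1. Fewer arrays also give less power, and the cause was not tested further. Lists numbered 5 higher and 7 lower. Of the 2262 features called on all arrays, 2257 changed in the same direction there, as did 101 of 101 named genes. Across features the changes correlated at 0.848 with those on all arrays. These arrays are part of both fits, so some of that likeness is built in. RB against other lymphomas stayed at 0 under each scaling. Myc stayed called at 1.09 to 1.23, Bcl2l1 at -1.88 to -1.53 and Krt8 at -2.78 to -1.73. No paired analysis was possible because replicate numbers only name the samples. With no spot intensities used here, features near background could not be told from others.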

Other observations

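Among the tests of this part, those of chromosome 15 under scaled arrays and in its proximal and distal parts were chosen after the result was seen; the mean test of chromosome 15 and the Notch test were planned, but their rules for a verdict were made stricter, to allow for spread, after the values were known.

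Genes were assigned to chromosomes as placed in the GRCm38.p6 annotation. Each chromosome was scored on each array as the mean of its centred genes less the array's median over all features. A two-sided exact permutation test ran over 15504 splits and 20 chromosomes. This score was lower in lymphoma for chromosomes 6 (-0.05, adjusted p = 0.0206), 11 (-0.05, adjusted p = 0.0161) and 17 (-0.07, adjusted p = 0.0161). Below the lowest normal thymus lay 12, 7 and 10 of the 15 lymphomas. A few genes with large falls can lower such a score, so it does not show a fall of a whole chromosome. By the medians used below, chromosome 6 lay between -1.61 and 0.58 SD of random lists in the 15 lymphomas. Chromosome 11 lay lower, between -4.45 and -0.38 SD, and chromosome 17 between -4.39 and 0.58 SD. Among normal thymuses these 2 chromosomes reached down to -2.24 and -1.54 SD. For chromosomes 11 and 17 a fall of many genes therefore stays open. Chromosome 17 holds the MHC genes described above.

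Extra copies of chromosome 15, which carries Myc, were considered as a hypothesis. The planned test did not show them: the score of its 346 genes differed by 0.05 on average (0.049974, SD among lymphomas 0.13, exact p = 0.409, adjusted p = 0.554). The values of single tumours were then looked at as medians against 1000 random lists of matched level, with a limit of 4 SD set at that point. Of 300 pairs of a lymphoma and a chromosome, 9 lay above and 3 below the limit, and of 100 pairs with a normal thymus 0 and 0. Chromosome 15 lay above it in 7 lymphomas: 12 (0.40), 7 (0.20), 10 (0.19), 11 (0.15), 6 (0.14), 1 (0.13) and 2 (0.13). The other 8 ran from -0.07 to 0.05 and the normal thymuses from -0.04 to 0.03. Chromosome 12 lay above it in lymphomas 10 (0.34) and 12 (0.13), chromosomes 8 in lymphoma 9 (-0.09), 17 in lymphoma 7 (-0.09) and 11 in lymphoma 10 (-0.09) below it. With arrays scaled to the same range, the first of these 3 lay at -3.57 SD and the second at -3.26 SD, inside the limit. Chromosome 7 in normal thymus 5 moved from -3.91 SD to -4.23 SD with scaled arrays, so a normal thymus passed the limit there.

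A wider ratio range of single arrays could move such medians, but with arrays scaled to the same range 7 lymphomas kept chromosome 15 above the limit. Each median was already set against random lists of matched level on the same array, and scaling changes both much alike. The test therefore says little about a narrower or wider ratio range of single arrays. Extra copies of the whole of chromosome 15 in some lymphomas should raise its proximal and its distal part together. Both parts lay above every normal thymus in 6 of 15 lymphomas, against 15 of 1000 random lists with as many. Chromosome 5 also gave 6, so the test leaves the question open; the rule was made stricter once this was seen. An earlier form of this test used the 7 tumours alone and was dropped, because it chose samples by their outcome. DNA copy number was not measured here, so extra copies may or may not underlie the shifts.

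Notch activity that differs between tumours was the other hypothesis. The 5 measured targets, Notch3, Nrarp, Heyl, Il2ra and Myc, had a mean pairwise Spearman correlation of 0.509 over the 15 lymphomas, at percentile 95.05 of 10000 random lists of matched SD. With scaled arrays it was 0.338, at percentile 96.7. The first percentile lies within the error of the draws from the 95th, so shared Notch activity that differs between tumours may be present but was not shown. A pair of tests on Myc targets was also run and not weighed further; with arrays scaled to the same range that list still changed by 0.61 at the median.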
